A study of Mus musculus with 5 samples.

How the data were processed

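Total RNA from 5 clones of mouse cardiac progenitor cells was measured on Affymetrix expression arrays, 1 array per clone. The cells had been isolated from adult left ventricles with an antibody to Sca-1, expanded and cloned, per the labels' protocols. RMA and GCRMA, which turn probe signals into probe set values, are named in the submitters' processing notes, without versions or roles. The deposited table holds a ratio on a linear scale for 45101 probe sets, as read from the values: no header or label states the unit. The median over the arrays was exactly 1 for 18926 probe sets (42.0%) and below 1 for the other 26175 (58.0%), and never above 1. The authors' values are therefore taken as each probe set divided by its own median or, where that median was low, by a floor, a division that the sources used here do not state. Expression levels, backgrounds and detection calls cannot be recovered from such values, and no array scanner files were used here. Depth in reads does not apply to arrays, and their number limits the precision.

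Probe sets were named from the array annotation supplied with the data, with symbols checked against a RefSeq gene table of assembly GRCm38.p6. Of the probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none; 64 control probe sets were left out of the gene values. Only probe sets with 1 symbol were used. The RefSeq table also gave the order of genes along the genome, used only in the closing section, and no coordinates are printed because no build was given with the data.

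The design fixed before the data were examined assumed expression levels, and parts of it had to change because the values were ratios. A probe set counted as measured if its median was exactly 1 or any clone lay above 1, which was the 95th percentile of the values of 83 probe sets of olfactory, vomeronasal and taste receptor genes, and if its range over the clones exceeded 0.05 log2 units. Flat probe sets, such as those held at the floor in all clones, carry no difference and were dropped. Even so, on 1832 of the 14457 remaining probe sets divided by their own median (12.7%) at least 4 clones lay within 0.02 log2 units, against 0.864% for normal errors with the spread of the hybridization controls. Some ratios recurred unchanged on many probe sets, 1 row of 5 on 356 of them, so clones tied in this way share a level and their closeness is no measurement. For 1141 measured genes every measured probe set had 4 clones tied; these genes held 12 of the 150 calls above the other clones and none of those below. The log2 ratios of a gene's measured probe sets were averaged, in place of the planned probe set with the highest mean, since a mean of ratios favours probe sets with 1 high array. The random lists were matched on the number of probe sets per gene and on the kind of divisor, in place of the mean level, and the range of Cxcl12 was ranked among all measured genes. A gene counted as lower in 1 clone only if it had a probe set divided by its own median. This left 9435 genes, 6388 of them on 1 probe set.

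Each clone formed its own group, and the clones were compared with one another. With 1 array per clone there is no residual degree of freedom, so no test and no p-value were computed. The measures were the range over the clones, the number of genes at least 1 log2 unit apart for each of 10 pairs, and the genes at least 1 log2 unit above or below all 4 other clones. Average-linkage clustering used 1 minus the Pearson correlation. For each of 36 gene lists the median deviation of a clone from the median of the others was set against 10000 random lists; a list stood apart below percentile 1 or above percentile 99, and lists with fewer than 5 measured members got no percentile. These percentiles describe these arrays only. The error of a value was taken from the 5739 pairs of probe sets that measure the same gene, whose clone deviations differed with a standard deviation of 0.42 log2 units and a median absolute difference of 0.13. In 2310 pairs at least 1 probe set ranged over 1 log2 unit or more, but only in 520 of these did both, and the median correlation over the clones in those 520 was 0.89. This error covers neither culture nor RNA preparation.

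Genes were named by a rule written before the data were examined: Cxcl12, its receptors Cxcr4 and Ackr3, and Kit, Ly6a and Pou5f1; for each clone the 5 genes farthest above and the 5 farthest below the nearest other clone; the 10 genes with the largest range; and up to 4 members of a described list with the largest range. Unnamed probe sets, predicted gene models and probe sets of several genes were excluded. In the lists that stood apart, the members farthest from the other clones in that clone were also named, a choice made after seeing the values, as was Vegfa.

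The calculations were tested on simulated ratios of 10576 genes built with the spread of 0.30 log2 units of a single probe set. Of 50 genes changed 4-fold in 1 clone 98% were recovered as specific to it, of 50 changed 2-fold 26%, since that fold equals the threshold, and of 50 changed 1.5-fold 4%; 6 of 10376 unchanged genes were called. A shifted list reached percentile 100, and 1 of 100 unshifted lists was called, against 5 of 100 with the spread of the hybridization controls. The simulated errors were normal and independent, and they held no culture or RNA error. The real differences between probe sets had wider tails (standard deviation 0.42, median absolute difference 0.13). These rates therefore do not carry over to the real calls. Alternatives covered array scaling, the probe sets allowed, the way they were combined, filters, the reference for a clone, the clustering method and the clones used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.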

Results

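RNA was profiled in 5 clones of cardiac progenitor cells, named 1D, 11B, 20B, 30 and 42. The cells came from the left ventricle of adult mice and were selected for Sca-1, a surface marker used to enrich progenitors. They are described as c-kit positive, c-kit being the stem cell factor receptor encoded by Kit. Each clone was measured on 1 Affymetrix expression array, so no group had a replicate, no difference could be tested, and every difference below has no replicate check. Differences were instead described by fixed sizes: 1 log2 unit, which is 2-fold, or 2 log2 units, which is 4-fold. The deposited values were ratios for 45101 probe sets, each divided by its own median over the arrays or by a floor, so they carried differences between clones but no expression level. Of 18193 named genes, 9435 had a probe set that could be followed between clones. The number of arrays limits the precision. The 18 hybridization control probe sets, which carry only array error, had a standard deviation of 0.08 log2 units. Probe sets of the same gene differed with a standard deviation of 0.42, which corresponds to a spread of 0.30 for a single probe set. Clone 11B stood apart in the RNA controls, with the lowest ratio of 5' to 3' signal for Actb (0.597 relative to clone 20B) and 18S signals of 0.411 to 0.555. For Gapdh the ratio was also lowest in clone 11B, at 0.924, but closer to the other clones, which lay between 1.00 and 1.16. In clone 30 the Actb ratio was 0.743, and in clone 42 the 18S signals were 0.651 to 0.955. Spiked poly-A controls were higher in clone 30 (median log2 0.33) and lower in clone 42 (median log2 -0.40).

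The first question, posed by the title of the series, was how far the clones differed in SDF-1, the chemokine encoded by Cxcl12 that attracts progenitor and endothelial cells through its receptor Cxcr4. Clone 11B had the highest Cxcl12 value. Its signal was 1.89-fold that of the median of the other clones on probe set 1448823_at and 2.82-fold on probe set 1417574_at, where most of them lay near the floor. Averaged over both probe sets, Cxcl12 in clone 11B lay 1.21 log2 units above the median of the other 4 clones, and 1.20 with values below the floor set to it. Clones 1D, 20B and 42 had ratios of 0.997, 1.00 and 1.001 on probe set 1448823_at. The same 3 ratios recurred in these clones on 376 other probe sets, so this was a shared level: their closeness did not measure Cxcl12, and the sizes of the differences from them were uncertain. Clone 30 had the lowest average, -0.89 log2 units relative to the others, but its probe sets disagreed: the ratio was 0.307 on probe set 1448823_at and 0.974 on probe set 1417574_at. Clones 1D, 20B and 30 were all near the floor on the latter, so a lower level there could not have been seen. The remaining probe set, 1439084_at, did not rise above the floor in any clone. The range of Cxcl12 over the clones was 2.07 log2 units, larger than that of 98.6% of the measured genes, and the excess in clone 11B was larger than the spread of 0.30 between probe sets. With the floor-level probe set included in the average, the values became 0.84 in clone 11B and -0.57 in clone 30.

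**Figure D1:**
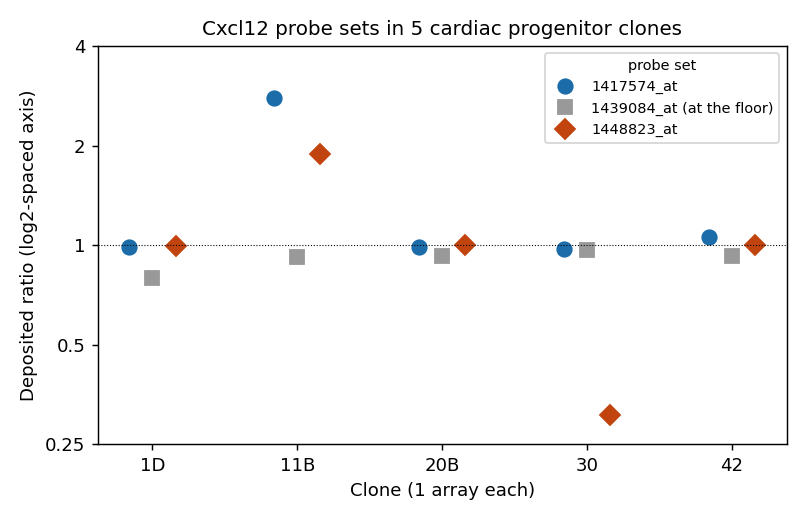
Deposited ratio (vertical axis, log2-spaced) of the 3 Cxcl12 probe sets in each of the 5 clones (horizontal axis, 1 array each, 1 point per probe set). Clone 11B has the highest value on 2 probe sets, at 2.78 and 1.889, and clone 30 the lowest on 1 of them, at 0.307.

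The receptors of SDF-1 could hardly be followed. Cxcr4 did not rise above the floor in any clone, with ratios of 0.768 to 0.779. Ackr3, which encodes the scavenging receptor of the same chemokine, was highest in clone 1D at a ratio of 1.138 and lowest in clone 42 at 0.845, while clones 11B and 30 had ratios shared with 1921 other probe sets. Among the markers used to define the cells, Kit had 1 measured probe set, with clone 20B at 1.183. The other clones lay between 0.991 and 1.002, ratios that recurred on 30 other probe sets, so differences among them could not be read. Pou5f1, the gene of the pluripotency factor oct-4, did not rise above the floor, at 0.572 to 0.580. No probe set was assigned to Ly6a, the gene of Sca-1, alone. A position at the floor did not show absence of a transcript: 9 of 43 genes named as ribosomal proteins, most of which every cell makes, also had only probe sets at the floor.

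Across all genes, the question was how widely the clones differed. Among the 10 genes with the largest ranges, Col3a1, a fibrillar collagen, came first at 6.57 log2 units, from 0.24 in clone 1D to -6.33 in clone 42. Cd81, a tetraspanin of the cell surface, was next at 6.18, with -4.38 in clone 30 and -4.37 in clone 42 against 1.80 in clone 20B. That order depended on the setting: the 2 ranges were 5.51 and 7.17 with quantile normalization, and 3.32 and 6.18 with every probe set averaged. Lama5, a laminin chain of basement membranes, was also lower in clones 30 and 42, at -3.11 and -2.73, than in clone 1D, at 1.66. Cdh13, the gene of T-cadherin, was higher in clones 30 (2.47) and 42 (2.29) and lower in clone 11B (-1.86). Mmp3, a matrix metalloproteinase, ran from -2.90 in clone 30 to 1.65 in clone 42, and Inhbb, a subunit of activin, from -2.90 in clone 1D to 1.98 in clone 30. Aldh3a1, an aldehyde dehydrogenase, spanned 5.59 log2 units, Trim27 5.54, Nbea 5.22 and Ppp4c 5.03.

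In total, 1229 of the 9435 measured genes (13.0%) had a range of at least 1 log2 unit and 143 had a range of at least 2. The median gene ranged over 0.41 log2 units, a 1.33-fold difference between its highest and lowest clone. Flat probe sets had been dropped before, and over all probe sets divided by their own median, flat ones included, the median range was 0.28. With a spread of 0.30 for a single probe set, ranges of this size do not show that the typical gene differed between clones. The counts of genes depended on how probe sets were combined. With every probe set of a gene averaged, 681 genes reached 1 log2 unit and 84 reached 2. Without clone 30 the counts were 772 and 72.

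The next comparison asked which genes set a single clone apart from all 4 others by at least 1 log2 unit. Clone 1D had 20 genes above and 13 below the other clones. The highest were Nbea, a scaffold of vesicle trafficking, 6.75-fold above the next clone, and Trim59, of the tripartite motif family, 6.55-fold. Shox2, a homeobox factor of the cardiac pacemaker region, was 3.37-fold higher, Kpna4, a nuclear import receptor, 3.05-fold, and Nmd3, an export adaptor of ribosomal subunits, 2.68-fold. Trim27 was lowest, with a log2 gap of -4.77 to the next clone over 3 probe sets, all marked for cross-hybridization. Inhbb followed at -2.42, Zkscan3 at -1.90, Stard3nl at -1.66 and Prss22 at -1.43. The deviation of Zkscan3 from the median of the others, -2.04, became -0.16 without probe sets marked for cross-hybridization, and that of Nmd3 fell from 1.66 to 0.83 with every probe set averaged.

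Clone 11B had 24 genes above and 20 below the others. Frmd4a, a scaffold protein of cell polarity, was 3.93-fold above the next clone. Eif4ebp2, a repressor of translation initiation, was 2.90-fold higher, Eqtn 2.82-fold, Celf2, an RNA-binding regulator of splicing, 2.67-fold, and Supv3l1, a mitochondrial RNA helicase, 2.62-fold. The lowest were Ppp4c, a protein phosphatase subunit, with a log2 gap of -3.39, Dusp6, a phosphatase of ERK, at -3.30, and Frg1 at -2.26, each on 1 probe set. Cdh13 was lower by a gap of -1.75 over 3 probe sets and the histone gene H2ac19 by -1.71. On H2ac19 probe sets 1418366_at and 1418367_x_at, clones 1D, 20B and 42 had ratios that recurred on 376 and 41 other probe sets. On that of Dusp6, clones 1D, 20B and 30 had ratios that recurred on 12 others. These were shared levels, so the sizes of the gaps of H2ac19 and Dusp6 are uncertain. With every probe set averaged, the deviations of Eif4ebp2, Eqtn, Celf2 and Supv3l1 fell from 1.58, 1.52, 1.46 and 1.68 to 0.39, 0.51, 0.62 and 1.00, so of the named high genes only Frmd4a kept its call, and that of Celf2 was 0.09 without cross-hybridizing probe sets. This clone also had the lowest Actb 5' to 3' ratio (0.597).

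Clone 20B had 15 genes above and 3 below the others, the fewest in the main setting, and 29 above and 4 below with quantile normalization. P4htm, a membrane-bound prolyl hydroxylase, was 5.08-fold above the next clone, Yme1l1, a protease of the mitochondrial inner membrane, 4.48-fold, and Abi1, a regulator of actin assembly, 3.75-fold over 3 probe sets. Cd81 was 3.47-fold and Mcpt8, a mast cell protease gene, 2.88-fold above the next clone. The genes below were Stox2 at a log2 gap of -1.56, R3hcc1 at -1.08 and the transcription factor Tcf4 at -1.05 over 5 probe sets. With every probe set averaged, the deviation of Stox2 went from -1.69 to -0.29, that of Tcf4 from -1.19 to -0.997 and that of Yme1l1 from 2.81 to 0.72, and all 3 calls were lost.

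Clone 30 had the most, 61 above and 55 below, and with quantile normalization 37 above and 52 below. Cobl, an actin nucleator, was 7.60-fold above the next clone, Cryab, a small heat shock protein abundant in muscle, 6.65-fold, and Ptgis, the prostacyclin synthase, 5.69-fold. Anxa8 was 5.45-fold and Myrf 5.29-fold higher, but the deviation of Anxa8 fell from 2.45 to 0.72 without cross-hybridizing probe sets. Below the others were Mybl1 (-2.48), Ago1, an argonaute protein of RNA silencing (-2.41), Mmp3 (-2.31), Slc40a1, the iron exporter ferroportin (-2.27), and the homeobox gene Dlx2 (-1.94), all as log2 gaps on 1 probe set each.

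Clone 42 had 30 genes above and 29 below. The serine protease gene Prss22 was 4.02-fold above the next clone, and Hand2, a transcription factor of heart development, 3.29-fold. Slc17a6, a vesicular glutamate transporter, was 3.01-fold higher, Btbd3 2.90-fold and Dcaf7 2.88-fold. Col3a1 was lowest with a log2 gap of -6.12 to the next clone on 1 probe set. Aldh3a1 lay at -3.45, Pdlim1, an actin-associated protein, at -2.98, Olfml3 at -2.29, and Col1a1, which forms the main fibrillar collagen of the heart together with Col1a2, at -1.90 over 2 probe sets. With every probe set averaged, Dcaf7 fell from a deviation of 1.69 to 0.85 and Pdlim1 from -3.00 to -0.9997, and both lost their calls.

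**Figure D2:**
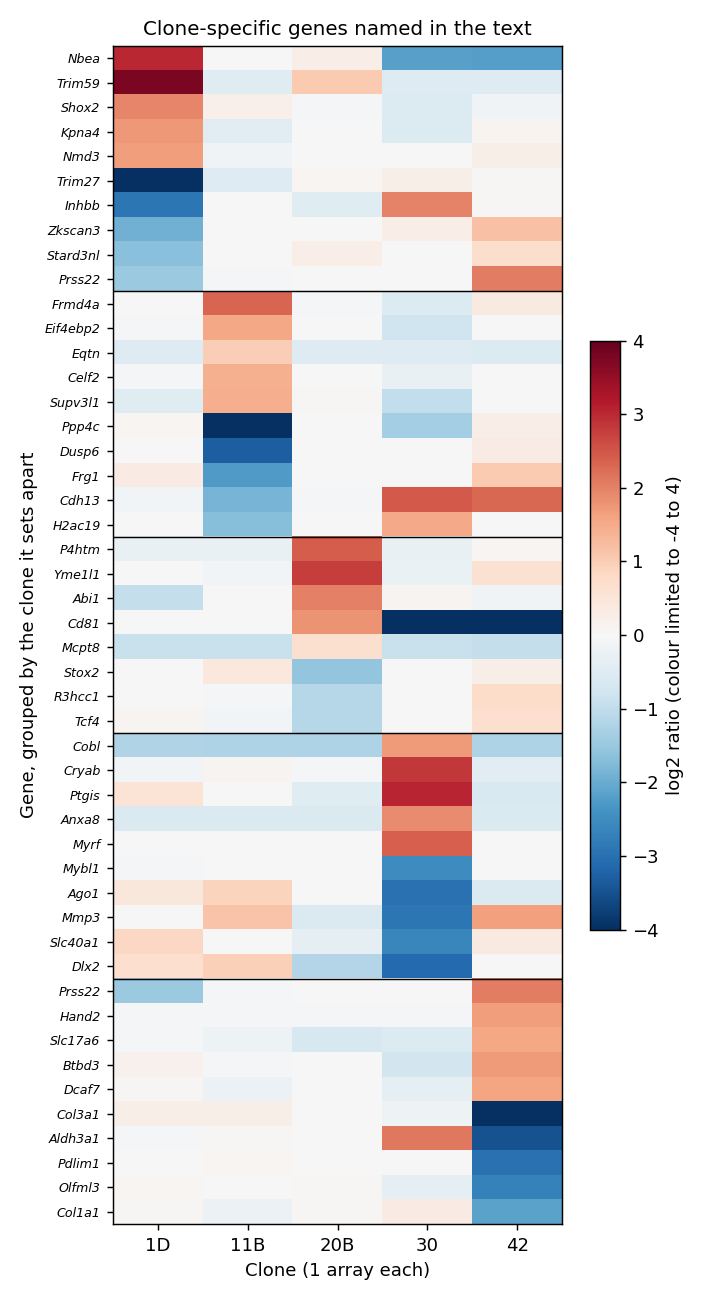
Log2 ratio (colour, limited to the range from -4 to 4) of the 48 named entries for genes that set 1 clone apart (rows, 1 black line between clones) in each of the 5 clones (columns, 1 array each). The lowest value, that of Col3a1 in clone 42, is -6.33.

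Altogether 270 calls set a clone apart, 150 above and 120 below. Of the 48 named entries, 31 rested on 1 probe set, and 10, Trim27, Col3a1 and Ppp4c among them, could not be measured without probe sets marked for cross-hybridization. For Eqtn, Mcpt8 and Cobl, and on 1 of 2 probe sets for Anxa8 and Hand2, the other clones lay below the floor within 0.10 log2 units of each other, a limit chosen after seeing the values, and for Myrf they were tied, so the sizes of these folds are uncertain. With values below the floor set to it, the deviations became 0.996 for Eqtn and 0.65 for Mcpt8, which lost their calls. Those of Cobl and Anxa8 became 1.71 (from 2.93) and 1.88. Trim59 and P4htm also had no probe set divided by its own median, so most of the other clones lay below the floor and the sizes of their folds are less certain. Both were not measured with own-median probe sets only, but kept their calls in the 9 settings that measured them. Averaging every probe set of a gene left 154 calls and 38 of the 48 entries, and using the probe set with the highest mean ratio gave 433. The latter rule is nearest to the planned one, which averaging of measured probe sets replaced once the values proved to be ratios.

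Pairs of clones were then compared directly. Clones 1D and 20B were the closest pair, with 59 genes at least 1 log2 unit higher in each. Clones 1D and 30 were the farthest, with 280 genes higher in clone 1D and 180 higher in clone 30. Clone 30 differed from clone 11B in 411 genes (222 higher in 11B), from clone 20B in 388 (242 higher in 20B) and from clone 42 in 385 (172 higher in 30). Clone 42 differed from clone 11B in 404 genes (220 higher in 42), from clone 20B in 283 (122 higher in 42) and from clone 1D in 242 (92 higher in 42). Clone 11B differed from clone 1D in 310 genes, with 100 higher in 11B, and from clone 20B in 160, with 52 higher in 11B. Hierarchical clustering, which the study's design names, joined clones 1D and 20B first, at a distance of 0.905. Clones 30 and 42, which shared low Cd81, Lama5 and Nbea, joined at 0.962, and clone 11B joined 1D and 20B at 1.03. The correlation of clones 30 and 42 (0.04) was barely above that of clones 1D and 42 (0.02). By number of genes, clone 42 was closer to clones 1D and 20B than to clone 30. Clones 1D and 20B also joined in 14 of 14 other settings, and clones 30 and 42 in 11 of them. Because each probe set was divided by its median, correlations between clones were near 0 or negative, from -0.24 to 0.09, and only their order was used. With every probe set of a gene averaged, the numbers of genes per pair were smaller, from 66 for clones 1D and 20B to 249 for clones 1D and 30.

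The last comparison asked which of 36 gene lists, fixed before the data were examined, stood apart in a clone. Matrix genes were low in clone 42. Of 16 measured collagens and matrix genes, 13 lay below the median of the other clones and 5 lay below it by at least 1 log2 unit. These were Bgn, the proteoglycan biglycan, at -2.12, Col8a1 at -1.89, Col6a2 at -1.29, Sparc at -1.23 and Col6a3 at -1.20. The probe sets of Sparc disagreed, at -3.00, -0.84 and 0.15. The list's median was -0.27, at percentile 0.00 among 10000 random lists of matched genes. Chemokines and cytokines were high in clone 30. Of 13 measured members 9 lay above the median of the others, led by Ccl2, which attracts monocytes, at 0.63, Lif at 0.62 and the neutrophil chemokine Cxcl1 at 0.52. Csf1 lay at -0.77, and the median was 0.18 at percentile 99.6. On probe set 1421207_at of Lif, clones 11B, 20B and 42 had ratios that recurred on 70 other probe sets, so the size of its deviation is uncertain. Genes of ribosomal proteins were low in clone 20B. Of 12 measured members 11 lay below that median, among them Rpl7 at -0.41, Rps18 at -0.33, Rps3 at -0.31 and Rpl13a at -0.30, with a median of -0.23 at percentile 0.00. These 3 lists stood apart in every alternative setting that gave them a percentile. The ribosomal list got none without probe sets marked for cross-hybridization, so that check was not possible for it.

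**Figure D3:**
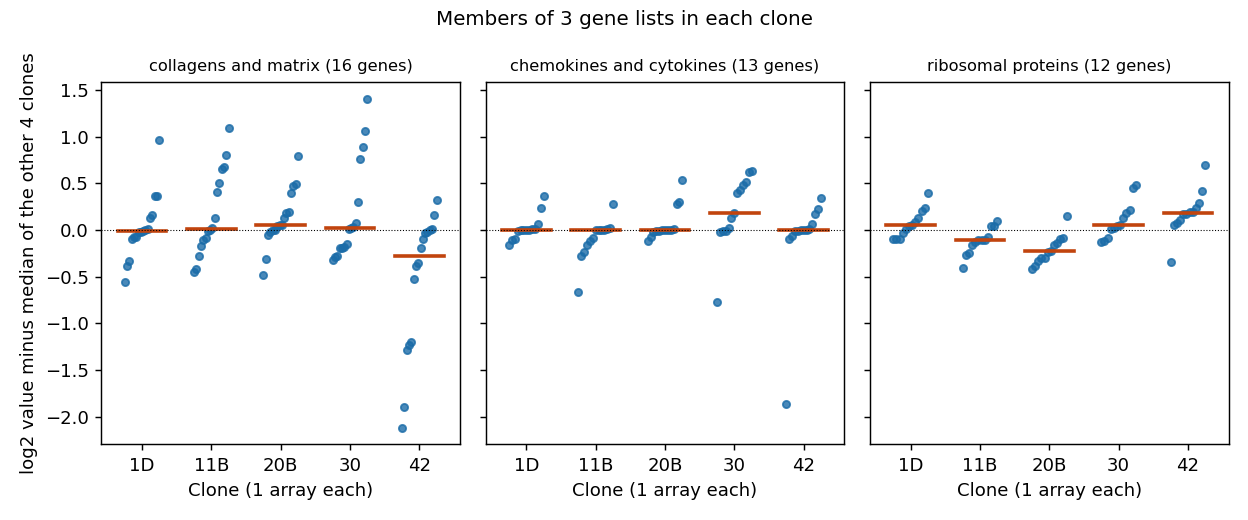
Log2 value of each member gene minus the median of the other 4 clones (vertical axis) for 3 gene lists in each clone (horizontal axis, 1 array each), with 1 point per gene and a line at the median. The medians are -0.27 for matrix genes in clone 42, 0.18 for chemokines and cytokines in clone 30 and -0.23 for ribosomal proteins in clone 20B, the last beside -0.11 in clone 11B and 0.18 in clone 42.

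Further lists stood apart in most settings. Genes of hypoxia and glycolysis were low in clone 1D, with a median of -0.21 over 14 genes at percentile 0.00. The glucose transporter Slc2a1 lay at -0.39, Hk2, a hexokinase, at -0.37, Ldha, lactate dehydrogenase, at -0.33 and Vegfa at -0.32. The same call was given by 15 of 16 settings. It was lost with the probe set of the highest mean ratio, the setting nearest to the planned rule, at percentile 25.8. The list of the TGF-beta and BMP pathway was also low in clone 1D, with a median of -0.18 at percentile 0.02 in the main setting and the same call in 15 of 16 others. Inhbb lay at -2.92 there, Smad6, an inhibitor of BMP signalling, at -0.75 and Id2 at -0.47, whereas Fst, which binds activin, lay at 0.25. In clone 30 the same list was high, with a median of 0.15 at percentile 99.3, Inhbb at 2.22 and Fst at 1.83, but only 10 of 16 settings kept that call. Immediate early genes were low in clone 11B. Egr1 lay at -0.92, Fos at -0.57 and Jun at -0.52, the median was -0.28 at percentile 0.03, and 15 of 16 settings gave the call. With the highest mean ratio the percentile was 2.1 and this call was lost. In the same clone, which had the lowest RNA control ratios, the 5 measured genes of cell cycle arrest and p53 targets had a median of -0.51. It lay at percentile 0.11, a call that 13 of 15 settings kept. The call was lost with the highest mean ratio (percentile 22.4) and with no filter (percentile 22.4). Cdkn1a, the inhibitor p21, lay at -1.14, Mdm2 at -0.97 and Cdkn1b at -0.51, while Phlda3 lay at 0.77.

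Cell cycle genes differed in small steps. Their median was 0.08 in clone 11B (percentile 99.5), -0.04 in clone 20B (percentile 0.54) and -0.07 in clone 30 (percentile 0.59). Pcna lay at -0.89 and Bub1 at -0.69 in clone 30, and Ccne1 at -1.07 in clone 20B, and each of the 3 calls was lost in at least 4 of 16 settings. Smooth muscle genes were low in clone 1D (median -0.21, percentile 0.34), with Smtn at -0.90 and Tagln at -0.49, a call that 11 of 15 settings kept and that turned to a median of 0.00109 with no filter. Adipogenic genes were low in clone 42 (median -0.36, percentile 0.21), with Pparg, the regulator of fat cell formation, at -1.77, but the median became 0.0130 without cross-hybridizing probe sets. Oxidative phosphorylation genes had a low median in clone 20B (-0.08, percentile 0.31), a call kept in 11 of 16 settings. Ndufa4 lay at -0.97 and Sdha at -0.91, but only 10 of 17 members lay below the other clones and 7 lay above. Secreted angiogenesis inhibitors had low medians in clones 1D and 42 (-0.18 and -0.19), with 4 and 5 of 7 members below the other clones. Only 6 and 7 of 16 settings kept these calls, and the median in clone 1D became 0.00802 without probe sets marked for cross-hybridization. Among lists with a percentile, those that varied most over the clones against random lists were fibroblast and mesenchymal genes (median range 0.90, percentile 99.6) and collagens and matrix (0.80, 99.5), each in 14 of 17 settings. Cell cycle arrest (1.12, 99.04) kept this call in 10 of 16 settings and immediate early genes (0.83, 99.1) in 6 of 17. In the first of these Loxl1, which encodes an enzyme that crosslinks elastin, ranged over 1.96 log2 units and the intermediate filament gene Vim over 1.46.

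Secreted angiogenic factors as a list did not stand apart in any clone, although 9 of 24 measured members ranged over at least 1 log2 unit. Adm, the vasodilator adrenomedullin, ran from -1.12 in clones 30 and 42 to 1.40 in clone 20B. Fgf7, a growth factor for epithelial cells, lay at -1.67 in clone 30, Angptl4 lay at -1.13 in clone 42, and Tgfb1 ran from -0.81 in clone 30 and -0.79 in clone 42 to 0.77 in clone 1D. Vegfa ranged over 0.52. Of 12 epicardial and mesothelial genes 4 could be followed, with a median of 1.00 in clone 30, where Krt8, a keratin, lay at 1.55, Upk3b, a uroplakin, at 1.19 and Msln, mesothelin, at 0.82. The remaining member, the keratin gene Krt18, lay below the median of the other clones there. The list's median in clone 30 was 0.40 without cross-hybridizing probe sets, and the list was too small for a percentile. Markers of other cell types were mostly not measurable: 3 of 22 endothelial genes, 1 of 9 pericyte genes, 4 of 18 leukocyte genes and 4 of 9 mast cell genes could be followed, and none of these lists was large enough for a percentile. Flt1, a VEGF receptor of endothelial cells, was the widest of the endothelial genes, ranging over 1.39 log2 units with 1.03 in clone 42. Among cardiac genes, Tnnc1, cardiac troponin C, ranged over 2.81 and Mef2c, a muscle transcription factor, over 1.81, and neither the cardiomyocyte list nor the list of cardiac transcription factors stood apart.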

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

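Of 3720 values recomputed under 21 alternatives, 3449 moved by less than the spread between probe sets or, for counts, by less than 1.5 times. Most of these values were list medians, mostly smaller than that spread themselves, so few of them could have moved. Among the counts, the Cxcl12 values and the tree, 72 moved and 304 did not. The following choices were made after seeing the data: averaging of measured probe sets in the main setting, own-median probe sets, flat probe sets kept, centring on measured probe sets, and clone-specific counts without a clone. The highest mean ratio was also added as an alternative then, but it is nearest to the planned rule. Centring each array moved no count beyond the limit of 1.5 times, since array medians differed by at most 0.02 log2 units. Dropping the filter changed the most values, 74 moved and 4 reversed, followed by averaging all probe sets, with 59 moved. With all probe sets of a gene averaged, and identically with no filter, 681 genes reached a range of 1 log2 unit and 84 a range of 2. The pairs of clones then differed in 149 genes (1D and 11B), 66 (1D and 20B), 249 (1D and 30), 134 (1D and 42), 75 (11B and 20B), 235 (11B and 30), 222 (11B and 42), 213 (20B and 30), 163 (20B and 42) and 215 (30 and 42), 1721 in sum. The 154 clone-specific calls, all among the 270, included 10 higher in 1D, 11 higher and 12 lower in 11B, 7 higher and 1 lower in 20B, 23 lower in 30 and 15 higher in 42; this follows from averaging in probe sets held at the floor. Cxcl12 became 0.84 in clone 11B and -0.57 in clone 30 under both and with the filter at the median of all values. In clone 30 it was -0.0679 on the probe set with the highest mean ratio and -1.70 on own-median probe sets. With the highest mean ratio, 265 genes reached 2 log2 units, pairs differed in 470 (1D and 11B), 214 (1D and 20B), 366 (1D and 42) and 264 (11B and 20B) genes, and 433 calls, 256 of them among the 270, included 67 higher in 1D, 45 higher and 35 lower in 11B, 27 higher in 20B and 58 higher in 42. Quantile normalization gave 29 genes higher in 20B and 37 in 30, and setting values below the floor to it gave 13 higher in 1D. Leaving out 1 clone gave 772 to 1067 genes at 1 log2 unit, 72 to 129 at 2 and 230 to 306 calls, the lowest each time without clone 30. Of the 3 groupings in the tree, 2 remained with no filter and with Euclidean distance and 1 with the highest mean ratio. The lists with the widest ranges numbered 7 with all probe sets averaged or flat ones kept and 2 with the highest mean ratio. Without probe sets marked for cross-hybridization the medians of angiogenesis inhibitors in 1D (0.00802) and adipogenic genes in 42 (0.0130) reversed, the first also with no filter (0.00406) and with the highest mean ratio (0.00802). With no filter, smooth muscle (0.00109) and TGF-beta genes (0.000610) in 1D and cell cycle genes in 11B (-0.000664) reversed, all to values near 0. Of 20 list calls, 3 held in every setting. For the remaining changes the cause was not tested. No paired analysis was possible because each clone had 1 array.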

Other observations

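The tests of chance gene order, of array scaling and of the probe set losses split by clone were chosen after the result was seen; the others were set down before it.

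Of the 48 named entries for genes that set a clone apart, 14 lay in runs of neighbouring genes that shifted together in that clone. All 5 genes named as highest in clone 1D (Nbea, Trim59, Shox2, Kpna4 and Nmd3) lay in 1 run of 44 neighbouring measured genes from Supt20 to Etfdh, with a median of 0.54 log2 units above the other clones. In clone 11B, Frmd4a and Celf2 lay in a run from Nmt2 to Prkcq (20 genes, median 0.49), and Eif4ebp2 and Supv3l1 in a run from Prf1 to Pbld2 (18 genes, 0.47). In clone 20B, Yme1l1 and Abi1 lay in a run of 10 genes with a median of 0.39 that was not found again after the density trend was removed or without cross-hybridizing probe sets, and 26 genes from Pfkp to Rala were higher at a median of 0.60. Trim27, Zkscan3 and Stard3nl, 3 of the 5 named low genes of clone 1D, lay in a run of 24 genes from Hecw1 to C230035I16Rik with a median of -0.19. Clone 42 had its largest low run from Yeats2 to Il1rap (33 genes, -0.48). Stretches of it were higher in clone 1D, from Parl to Polr2h (0.48), and in clone 20B, from Ephb3 to Il1rap (0.44). The stretch around Alcam, Tfg and Filip1l was low in clone 30 (-0.69) and in clone 42 (-0.40). Genes from Uhrf1 to Gpr108 were higher in clone 42 (0.54), whereas an overlapping run in clone 30 failed both of these checks.

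A candidate explanation for these runs is a gain or loss of chromosome segments in single clones during culture, or regulation shared by neighbours. Using windows of 10 genes ordered by assembly GRCm38.p6, 37 runs passed a limit that none of 1000 permuted gene orders approached in number, with at most 3 runs each. Several runs covered the same genes in different clones, such as those around Micos13 and Alcam, so they are not 37 separate regions. When runs were found on every other gene only, the genes left out shifted the same way by a median of 0.25 log2 units, against at most 0.01 in permuted orders. Gene density is argued against as the whole cause, since 30 of 37 runs were found again after its trend was removed. So are cross-hybridizing probe sets, since 23 of 37 were found again without them. A run counted as found again if a run of that clone and direction shared at least 1 gene with it, so much of a run could have been lost. Neither cause is excluded for the higher runs of clone 30, of which each check lost 5 of 7. No DNA was measured, so copy number and shared regulation stay open. The runs held 39 of the 270 clone-specific calls (14.4%), against 0.61% of all combinations of gene, clone and direction. This excess is partly built in, since the runs were found from the same deviations. Most calls lay outside the runs. Among higher calls the share inside was 30% in clone 1D, 45.8% in 11B, 46.7% in 20B, 6.56% in 30 and 6.67% in 42. Among lower calls it was at most 23.1%, in clone 1D.

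The excess of Cxcl12 in clone 11B could have followed from array scaling or from such a run. The median of the 20 nearest measured genes in clone 11B was 0.0136 log2 units, against 1.21 for Cxcl12, which argues against such a run. The median of all measured genes in clone 11B was -0.00145 log2 units. Array medians differed by at most 0.02 log2 units, so this median was bound to lie near 0 and could not decide on array scaling. RNA quality stays open, as clone 11B had the lowest Actb 5' to 3' ratio, and the difference between clones that the design names was not tested for want of replicates.

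Some of the steepest drops may reflect the loss of 1 probe set and not of the gene. Of 35 probe sets at least 4-fold below every other clone, 23 had other measured probe sets of the same gene, whose median was -0.40 in that clone, with quartiles of -1.05 and -0.004. Of 52 comparisons with these other probe sets, 28.8% also lay at least 1 log2 unit lower. Dropped probe sets of the same gene were also compared with each other, so those of Trim27 counted several times. The median and quartiles hold the same repeats. For 19 probe sets at least 4-fold above every other clone, 8 had others, and in 64.3% of 14 comparisons these lay at least 1 log2 unit higher (median 1.67). Probe sets of Abi1 and of Tuba4a counted repeatedly in the same way, so neither share is a share of separate probe sets. Genes with agreeing probe sets included Trim27 in clone 1D, at a median of -6.11 for its other probe sets, all of them marked for cross-hybridization, and Col1a1 in clone 42 (-1.01). By contrast, Lasp1 in clone 11B had 7 other probe sets at a median of 0.12 and Rbbp4 had others at -0.36. In clone 42 the other probe sets of Sparc had a median of -0.34. The median over genes was -0.36 in clone 11B and -0.42 in the other clones, so loss of a probe set and change of a gene cannot be told apart for the set as a whole: the values lay between the bounds set for each. Different transcript ends between clones were not tested.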
